A study of Mus musculus with 53 samples.

How the data were processed

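Single nuclei of the left hippocampal formation were profiled in 53 libraries from female mice of 14 strains, each of 5XFAD carrier or nontransgenic genotype and 6 or 14 months old. Strain, age and genotype of each library were taken from its title in the labels. There is at most 1 library per strain, age and genotype, so every library is a separate mouse and p-values measure the spread between mice of different strains. Resilience or susceptibility of strains was not used here, since the labels give it for no library.

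The deposited files of each library hold counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. Per the submitters' processing notes they were made with bcl2fastq 2.20.0.422 and Cell Ranger 3.1.0, while the matrix headers give software version 3.0.2. The notes list the builds mm10 and GRCh38. The features used here are 31053 mouse genes, the same in every library, and no feature of the human transgenes was among them, so a planned check on human transgene reads could not be done. Clec7a and C4a were not analysed here. Whether reads were counted by strand is not given in the sources used here. Gene positions came from GENCODE vM21 (GRCm38).

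The files held 241273 barcodes with 1498436478 UMIs. Nuclei were kept with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs; 21251 barcodes failed. Simulated doublets (30 neighbours, expected share 0.8% per 1000 nuclei) removed 8279 more, 3.76%, leaving 211743 nuclei. Kept nuclei numbered 57800 and 63407 in nontransgenic mice and carriers at 6 months and 51596 and 38940 at 14 months, and 703 to 6172 per library, with 5894497 to 48167707 UMIs and a median of 1242 to 9260 UMIs per nucleus. The mitochondrial percent averaged 1.16 ± 0.472, 1.12 ± 0.443, 1.06 ± 0.454 and 0.921 ± 0.355 (SD) in the same order of groups. Libraries stood apart when their median was under 3000 UMIs per nucleus, or when over 20% of their nuclei lay in 1 unnamed cluster and this was over 10 times the median over libraries; this definition was made after the data were seen.

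For clustering, counts were scaled to 10000 per nucleus and log transformed, and 2000 variable genes were chosen without any gene of the tested lists. From 600 nuclei per library, 30 principal components and a graph of 15 neighbours were computed and cut into 34 clusters with the Leiden method at resolution 1.0 (seed 1); the other nuclei joined the nearest cluster centre. Clusters were named by 14 lists of textbook markers (at least 3 markers, each detected in a share of at least 0.05, and a score margin of 0.2). This gave 13 named classes and 7 unnamed clusters with 13.99% of nuclei, which were used only in the denominator of shares. The named classes were dentate granule neurons (46164 nuclei), subicular or cortical pyramidal neurons (30372), oligodendrocytes (27015), CA1 pyramidal neurons (18090), astrocytes (15519), GABAergic neurons (14050), microglia (12155), CA2, CA3 or mossy neurons (8804), oligodendrocyte precursors (6262), vascular or meningeal cells (2190), Cajal-Retzius neurons (760), perivascular macrophages (523) and ependymal or choroid plexus cells (225). Genes that name a class are not reported as findings of that class, except where they stand beside its share or belong to a list.

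UMIs were summed per library and class where a library had at least 20 nuclei, and a class was tested when at least 8 libraries per group remained. This left 10 classes; vascular or meningeal cells rested on 48 libraries. Sums were tested with edgeR 4.0.16 quasi-likelihood F tests (TMM scaling, filterByExpr, robust dispersion) with a term for each of the 4 groups and for strain. The contrasts were genotype at 6 months, genotype at 14 months, age in nontransgenic mice, age in carriers and the difference of the genotype effect between ages, and strain was tested over all its terms. A gene was called when its Benjamini-Hochberg adjusted p, within a class and contrast, was under 0.05. The standard error beside a log2 fold change is its absolute value divided by the square root of the F statistic. Levels in a class are CPM, counts relative to the TMM-scaled UMI total of its tested genes in a library, with the SD over libraries. Levels over all nuclei are relative to the unscaled UMI total of the library.

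Strain pairs the libraries, and the pairing comes from the titles. As a check on it, after group means were removed from log counts of dentate granule neurons, 76 pairs of libraries of 1 strain had a median correlation of 0.126 (lowest -0.433), against -0.0167 over 976 pairs of different strains and groups, and 18 of 53 libraries matched their own strain best. No 2 of 326 pairs of libraries within a group held the same counts, the lowest chi-square per degree of freedom being 6.39.

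The text names genes by a rule fixed before the data were examined: per class, the 4 higher and 4 lower called genes of smallest p for genotype at each age and for age in nontransgenic mice, 2 and 2 for the other contrasts, 3 per class for strain, and 4 members per list of smallest p, passing over symbols without a gene name, and always Thy1, App, Calb1 and Gpnmb. A few genes that the rule names are not reported here. Piezo2, genes that named classes, and the genes of the chromosome 3 window were named after their values were seen. Ermard, Rap1gapos and Kcnab1, which overlap other genes, and genes with near-identical copies are uncertain.

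The 19 textbook gene lists were plaque-associated microglia, homeostatic microglia, interferon response, antigen presentation, complement, reactive astrocyte, homeostatic astrocyte, disease-associated oligodendrocyte, myelin, cholesterol biosynthesis, neuronal activity-regulated, glutamatergic synapse, nuclear-encoded oxidative phosphorylation, heat shock and chaperone, unfolded protein response, mouse counterparts of Alzheimer's risk genes, immature granule neuron, proliferation, and vascular and blood-brain barrier; none was chosen on these samples. They made 68 pairs of a list and a class, tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted within a contrast. Exchanging labels gave as many pairs at the preset correlation in every contrast except age in carriers, so a list is described as higher or lower only where its call held with a correlation estimated from the data. With that correlation exchanges still gave as many for both age contrasts and for the difference.

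Class shares are percents of all kept nuclei, compared as log2 ratios within a strain (0.5 nuclei added) by exact two-sided sign-flip tests and adjusted over 13 classes. Markers of other classes were compared within each class in the same way. RNA from other cells was examined in genes higher in at least 3 classes other than microglia. Microglia had at least 3 times the UMIs per nucleus of any other class for them. Windows of 20 Mb in steps of 5 Mb with at least 50 genes were ranked by the share of genes called outside microglia and compared with 10000 shuffles of gene order.

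Tested on simulated data, with negative binomial counts at the depth and dispersion of the real libraries, the 14-month genotype test recovered 53.7%, 92.5% and 97.0% of changes of 0.5, 1 and 2 in CA1 neurons, 28.4%, 82.1% and 97.0% in microglia, 35.8%, 94.0% and 100% in oligodendrocytes and 10.4%, 56.7% and 97.0% in vascular or meningeal cells, with 0 genes called in an unchanged comparison. Of the 175, 152, 156 and 116 genes called there, 13, 14, 3 and 7 were unchanged ones.

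Alternatives planned before the data were examined were DESeq2 1.42.0, RLE scaling, no filter on low counts, no strain term, a term for library run (15 runs of neighbouring library numbers, which the labels do not call batches), only the 2 groups of a contrast, at least 50 nuclei per library, a stricter nucleus filter (1000 UMIs, 700 genes, 1% mitochondrial), doublets kept, resolution 2.0 (52 clusters), omission of C57BL6J and C57BL6JxD2Gpnmb, and omission of each strain in turn. For lists they were an estimated correlation and fry, and for shares an unpaired permutation test (100000 resamples) and a centred log ratio. Omission of the 7 libraries that stood apart was added after the data were seen. To ask how often chance gives as many calls, the group labels were exchanged among the libraries of each strain in 24 draws. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3.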

Results

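Nuclear RNA was profiled from the frozen left hippocampus of 53 female mice by droplet sequencing of 3' transcript ends, 1 library per mouse. Carriers of 5XFAD, which includes mutant human APP expressed from the Thy1 promoter, were compared with nontransgenic mice of the same genetic backgrounds at 6 and 14 months of age. The 14 backgrounds, termed strains here, were 12 crosses of C57BL6J with different BXD recombinant inbred lines, the cross C57BL6JxD2Gpnmb and inbred C57BL6J. There were 13 nontransgenic and 14 carrier libraries at 6 months, and 14 nontransgenic and 12 carrier libraries at 14 months, with at most 1 library per strain, age and genotype. Both genotypes were present in 13 strains at 6 months and in 12 strains at 14 months.

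After filtering, 211743 nuclei with 1360957644 unique molecular identifiers (UMIs) remained. The total per library ranged from 18886039 to 48167707 UMIs in 6-month nontransgenic mice, from 5894497 to 40056903 in 6-month carriers, from 11084050 to 37885817 in 14-month nontransgenic mice and from 9531605 to 38630728 in 14-month carriers. Median UMIs per nucleus averaged 5835 ± 1273 (SD, n = 13), 5868 ± 1208 (n = 14), 5001 ± 2058 (n = 14) and 5483 ± 2383 (n = 12) in the same order. There were 7 libraries that stood apart, and 4 of them were among the 12 carriers at 14 months. Of the 7, 6 had medians of 1242 to 2604 UMIs per nucleus. The C57BL6JxBXD113 carrier at 14 months had 24.85% of its nuclei in 1 unnamed cluster, against a median of 1.52% over libraries.

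Thy1, a neuronal surface glycoprotein whose sequence is part of the transgene cassette, separated carriers from nontransgenic mice in every library. Over all nuclei it stood at 58.0 ± 8.10 CPM (counts relative to the UMI total of a library) in nontransgenic mice and 215.1 ± 58.5 CPM in carriers at 6 months, and at 54.5 ± 8.73 and 178.4 ± 45.0 CPM at 14 months. The lowest carrier had 111.5 CPM and the highest nontransgenic mouse 74.3 CPM. The paired log2 difference was 1.87 ± 0.42 (SD, 13 of 13 strains, exact two-sided sign-flip p = 0.000244) at 6 months and 1.68 ± 0.47 (12 of 12 strains, exact p = 0.000488) at 14 months, each p being the smallest these pairs can give. App was higher by 0.10 (11 of 13 strains, exact p = 0.000977) and 0.12 (11 of 12, exact p = 0.0083) at the 2 ages. Cassette and mouse Thy1 reads could not be separated. Human transgenes were not analysed, so App may include human APP reads.

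**Figure D1:**
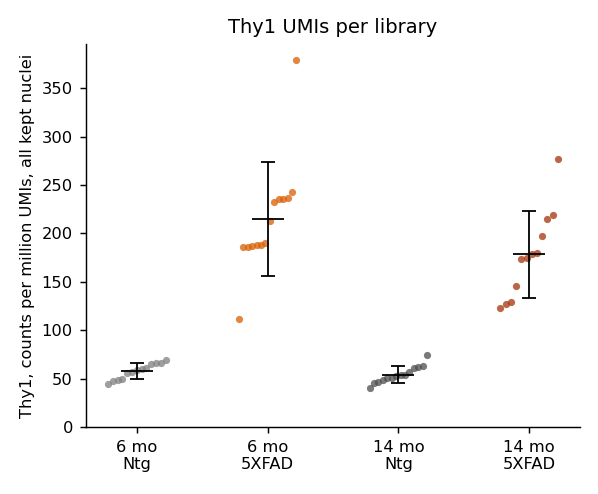
Thy1 in CPM over all kept nuclei, 1 point per library in the 4 groups, with the mean and SD. Every carrier library lies above every nontransgenic library at both ages, the lowest carrier at 111.5 and the highest nontransgenic library at 74.3.

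The first question was whether the transgenes were accompanied by a change in cellular makeup. Microglia made up 3.29 ± 0.50% of kept nuclei in nontransgenic mice and 8.29 ± 1.90% in carriers at 6 months, and 3.64 ± 0.68% and 8.17 ± 2.29% at 14 months. Astrocytes were lower in carriers, at 6.77 ± 1.25% against 9.23 ± 2.05% at 6 months and 4.63 ± 2.17% against 8.24 ± 2.65% at 14 months. At 14 months CA1 pyramidal neurons were 5.81 ± 2.05% of nuclei in carriers and 8.95 ± 1.79% in nontransgenic mice, and perivascular macrophages were 0.437 ± 0.301% against 0.154 ± 0.0994%. All are means ± SD over the libraries of a group.

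Paired by strain, the log2 ratio of the microglial share was 1.37 ± 0.38 (SD, higher in 13 of 13 strains, adjusted p = 0.00317) at 6 months and 1.14 ± 0.44 (12 of 12 strains, adjusted p = 0.00317) at 14 months. The astrocyte share changed by -0.40 ± 0.40 (lower in 10 of 13 strains, adjusted p = 0.027) and -1.01 ± 0.76 (12 of 12 strains, adjusted p = 0.00317). The 6-month astrocyte call was lost when any of 7 strains was left out. For CA1 neurons the ratio at 14 months was -0.69 ± 0.87 (lower in 10 of 12 strains, adjusted p = 0.0222), and for macrophages it was 1.44 ± 1.34 (higher in 10 of 12 strains, adjusted p = 0.0148). At 6 months the CA1 ratio was 0.06 ± 0.36 (adjusted p = 0.701), and the paired difference between ages was -0.75 ± 0.77 (lower in 10 of 12 strains, adjusted p = 0.0317). Among carriers alone the CA1 share was lower at 14 than at 6 months by a log2 ratio of -0.71 ± 0.79 (11 of 12 strains, adjusted p = 0.019), and no class share passed for age in nontransgenic mice (lowest adjusted p = 0.279). The call for the difference between ages was lost with the centred log ratio, at clustering resolution 2.0, without C57BL6J and C57BL6JxD2Gpnmb and when any of 10 strains was left out. The CA1 calls at 14 months and among carriers were lost at resolution 2.0 and without C57BL6J and C57BL6JxD2Gpnmb, and the macrophage call without these. With a stricter nucleus filter, which removes most glia, no microglial, astrocyte or macrophage share passed at either age. These are exact two-sided sign-flip tests, adjusted over 13 classes within a contrast.

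Of the CA1 markers, Spink8 (-0.71) and Ndst4 (-0.50) were lower in CA1 nuclei of 14-month carriers. Unnamed cluster 15 held 4.75% of carrier and 2.60% of nontransgenic nuclei then, but 8.685 to 23.75% in libraries of few UMIs (median of all 0.326%). No link to the CA1 share was tested. Without the 7 libraries no class share passed at 14 months. The CA1 ratio was then -0.53 (adjusted p = 0.152), the microglial ratio 1.29 and the astrocyte ratio -0.54 (both adjusted p = 0.102). With the 7 strains left no exact p falls below 0.0156, at which a class alone fails adjustment, so these losses decide nothing.

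**Figure D2:**
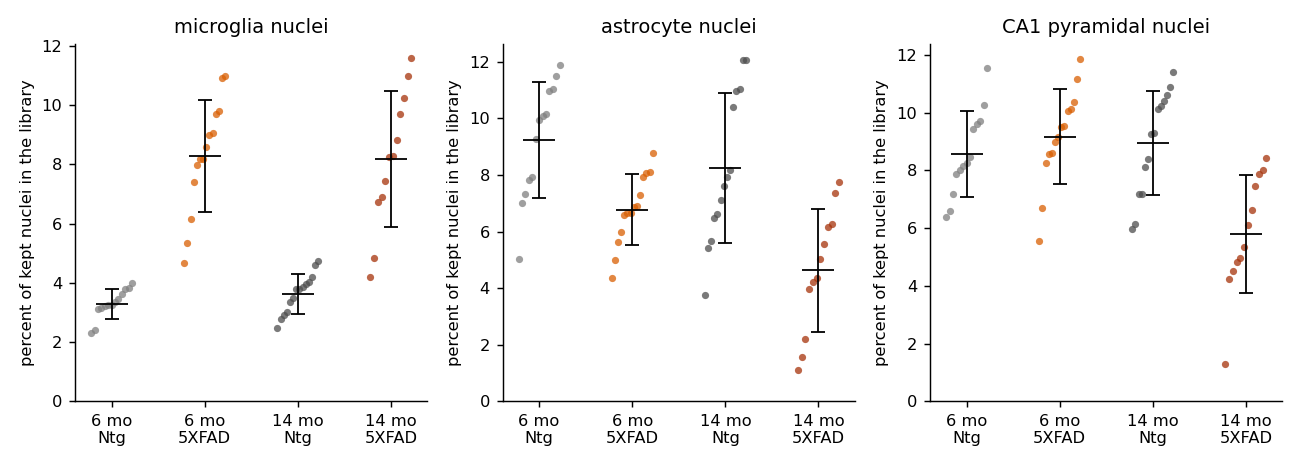
Microglia, astrocytes and CA1 pyramidal neurons as a percent of kept nuclei, 1 point per library in the 4 groups, with the mean and SD. The mean of microglia is higher and that of astrocytes lower in carriers at both ages, and the mean of CA1 neurons is lower in carriers at 14 months. The 6-month astrocyte call was lost when any of 7 strains was left out.

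In carriers at 6 months, microglia, astrocytes, the oligodendrocyte lineage and CA1 pyramidal neurons carried most of the changed genes. In microglia the cystatin gene Cst7, which encodes a lysosomal protease inhibitor, stood at 63.1 ± 20.2 CPM in carriers (SD, n = 14) and 0.441 ± 1.10 CPM in nontransgenic mice (n = 13). P2ry12, the ADP receptor of surveying microglia, was at 497.3 ± 50.1 against 734.6 ± 98.6 CPM. Complement C4b was 12.3-fold higher in oligodendrocytes, at 230.4 ± 87.1 against 18.2 ± 7.43 CPM. Gfap, the intermediate filament of reactive astrocytes, was at 477.6 ± 124.8 against 194.8 ± 65.1 CPM in astrocytes. Sqle, which encodes squalene epoxidase of cholesterol synthesis, was at 38.4 ± 8.19 against 14.7 ± 3.83 CPM in CA1 neurons.

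Of 111157 tests of a gene in 1 of 10 classes, 1564 passed an adjusted p of 0.05 at 6 months (edgeR, Benjamini-Hochberg), 1127 higher and 437 lower in carriers, in 1358 different genes. Microglia gave 1106 of them (703 higher, 403 lower), CA1 pyramidal neurons 128 (105 and 23), astrocytes 101 (99 and 2), oligodendrocyte precursors 92 (88 and 4) and oligodendrocytes 78 (75 and 3). There were 22 in dentate granule neurons (all higher), 21 in subicular or cortical pyramidal neurons (20 and 1), 10 in GABAergic neurons (9 and 1), 5 in CA2, CA3 or mossy neurons (all higher) and 1 in vascular or meningeal cells. Whether an effect differed between classes was not tested. Below, changes are log2 fold changes of carriers against nontransgenic mice ± SE, with adjusted p from edgeR and the number of strains, of 13, in which the carrier was higher or lower.

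Among microglial genes, Etl4 (ENSMUSG00000036617; 3.33 ± 0.14, adjusted p = 6.54e-23), the olfactory receptor gene Olfr111 (3.72 ± 0.18, 7.12e-21), Cst7 (ENSMUSG00000068129; 6.24 ± 0.37, 2.04e-19) and the pyrophosphate transporter gene Ank (3.07 ± 0.17, 1.31e-18) had the smallest p among those higher, each in 13 of 13 strains. The B-cell adaptor gene Bank1 (-1.62 ± 0.14, 2.49e-13), the protein kinase C gene Prkca (-0.93 ± 0.08, 3.67e-12), Lrba (-0.79 ± 0.08, 4.77e-11) and Ecscr (-1.71 ± 0.17, 6.55e-11) had the smallest among those lower, each in 13 of 13 strains. Of 37 tested genes of plaque-associated microglia, 36 rose, and 36 did so when adjusted over the list alone (camera adjusted p = 5.01e-83, and 3.52e-08 with an estimated correlation), with a median of 1.86. They included Apoe (0.99 ± 0.15, 13 of 13 strains), the lipid receptor gene Trem2 (0.94 ± 0.11, 13 of 13), the Wnt modulator gene Dkk2 (5.51 ± 0.47, 13 of 13) and the glycoprotein gene Gpnmb (3.37 ± 0.77, 10 of 13). Of 24 homeostatic microglial genes, 15 fell, and 16 when adjusted over the list alone (adjusted p = 6.39e-10, and 0.0342 with an estimated correlation; median -0.41), among them P2ry12 (-0.55 ± 0.08), the fractalkine receptor gene Cx3cr1 (-0.44 ± 0.08) and the fructose transporter gene Slc2a5 (-0.71 ± 0.15). In microglial nuclei of carriers perivascular macrophage markers were lower (-1.14, adjusted p = 0.037) and vascular markers higher (0.55, 0.037), and CA1 (-0.41, 0.0317) and dentate granule markers (-0.43, 0.037) were lower.

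Interferon-response genes rose in 3 glial classes at 6 months. All 18 tested in microglia rose, and 18 when adjusted over the list alone (adjusted p = 0.000517 with an estimated correlation; median 1.51), led by Oasl2 (4.67 ± 0.43, 13 of 13 strains), Sp100 (2.63 ± 0.22) and the deubiquitinase gene Usp18 (3.20 ± 0.34). In astrocytes 11 of 13 rose, and 12 adjusted over the list alone (4.01e-09 with an estimated correlation; median 1.04), with Oasl2 at 3.51 ± 0.44 and Ifit3 at 1.99 ± 0.30, each higher in 12 of 13 strains. In oligodendrocytes 5 of 8 rose, and 6 adjusted over the list alone (3.21e-05 with an estimated correlation), including Rtp4 (1.34 ± 0.20, 12 of 13). In vascular or meningeal cells none of 10 passed (adjusted p = 0.42). Antigen presentation genes rose alongside: 7 of 10 in microglia (9 adjusted over the list alone; 5.5e-05 with an estimated correlation), 5 of 6 in oligodendrocytes (5 and 4.66e-07) and 5 of 6 in astrocytes (6 and 1.58e-07). They included the class I genes H2-D1 (2.11 ± 0.16) and H2-K1 (1.97 ± 0.14) in microglia and the class II chaperone gene Cd74 (2.51 ± 0.40, 13 of 13 strains) there. H2-D1, H2-K1, Oasl2 and Olfr111 have close relatives in the genome, so the division of reads among family members is uncertain.

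In astrocytes the genes with the smallest p were Gfap (ENSMUSG00000020932; 1.30 ± 0.12, adjusted p = 5.79e-10, 13 of 13 strains), the helicase gene Ddx60 (2.33 ± 0.24, 1.33e-09, 12 of 13), C4b (1.38 ± 0.14, 1.06e-08, 13 of 13) and H2-D1 (1.53 ± 0.17, 1.71e-08, 13 of 13). Of 23 reactive astrocyte genes 14 rose, and 20 adjusted over the list alone (5.47e-07 with an estimated correlation; median 0.60), including the protease inhibitor gene Serpina3n (1.66 ± 0.29, 13 of 13) and Clu (0.64 ± 0.15, 13 of 13). The genes that fell were Necab3 (-0.49 ± 0.13, adjusted p = 0.0491, 10 of 13 strains) and Strn4 (-0.40 ± 0.11, 0.0494, 9 of 13). Of 17 homeostatic astrocyte genes 2 rose and none fell (3 higher adjusted over the list alone; adjusted p = 0.0654). The calls of Clu and Necab3 were lost without the 7 libraries, that of Serpina3n with library run as a term and that of Strn4 without C57BL6J and C57BL6JxD2Gpnmb.

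C4b led both stages of the oligodendrocyte lineage, at 3.63 ± 0.18 (adjusted p = 3.55e-18) in oligodendrocytes and 3.47 ± 0.24 (4.59e-18) in precursors, in 13 of 13 strains each. Oligodendrocytes also had higher Aldh1l2, a mitochondrial folate enzyme gene (1.67 ± 0.16, 2.2e-10), H2-D1 (1.92 ± 0.20, 4.04e-09) and H2-K1 (1.72 ± 0.20, 1.94e-08), each in 13 of 13 strains. Lower in oligodendrocytes were Kcnab2, a potassium channel subunit gene (-0.57 ± 0.13, 0.0155, 13 of 13), the solute carrier gene Slc5a11 (-0.64 ± 0.15, 0.0155, 12 of 13) and Impdh1 of guanine nucleotide synthesis (-0.96 ± 0.23, 0.0181, 12 of 13). Of 12 disease-associated oligodendrocyte genes 5 rose, and 9 adjusted over the list alone (3.15e-09 with an estimated correlation; median 0.80). Of 21 myelin genes 1 rose, Cldn11 of the tight junction (0.36 ± 0.09, 12 of 13 strains); 1 did so when adjusted over the list alone, and the list test had adjusted p = 0.299 with an estimated correlation. In precursors Ddx60 rose (2.68 ± 0.32, 1.11e-07, 13 of 13) and Grk3, a receptor kinase gene, fell (-0.70 ± 0.15, 0.00523, 10 of 13). The calls of Kcnab2 and Impdh1 were lost without C57BL6J and C57BL6JxD2Gpnmb.

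In CA1 neurons the whole cholesterol synthesis list rose. After Thy1 (ENSMUSG00000032011; 2.35 ± 0.08, adjusted p = 1.85e-28), the smallest p values belonged to the sterol dehydrogenase gene Nsdhl (ENSMUSG00000031349; 1.77 ± 0.12, 1.96e-15), Sqle (ENSMUSG00000022351; 1.44 ± 0.12, 9.26e-13) and the squalene synthase gene Fdft1 (0.96 ± 0.08, 9.06e-12). Mvd (1.80 ± 0.17) and Dhcr7 (1.13 ± 0.11) of this pathway followed, all 6 higher in 13 of 13 strains. All 22 tested members rose, and 22 when adjusted over the list alone (3.67e-11 with an estimated correlation; median 1.18). The list was also higher in CA2, CA3 or mossy neurons (0 of 22 called, 17 adjusted over the list alone, 6.69e-05 with an estimated correlation; median 0.39), in subicular or cortical neurons (3 and 13, 0.000113; median 0.30) and in GABAergic neurons (0 and 0, 0.0157; median 0.15). It was not in dentate granule neurons, oligodendrocytes or astrocytes (adjusted p = 0.661, 0.403 and 0.848). Lower in CA1 neurons were the cyclin gene Ccnd2 (-0.83 ± 0.11, 9.15e-07, 13 of 13 strains) and the carbonic anhydrase gene Car4 (-0.86 ± 0.13, 7.91e-06, 13 of 13). So was the exchange factor gene Arhgef26 (-0.44 ± 0.09, 0.0035, 12 of 13). Astrocyte markers were 0.26 higher on the log2 scale in CA1 nuclei of carriers (12 of 13 strains, adjusted p = 0.0317).

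**Figure D3:**
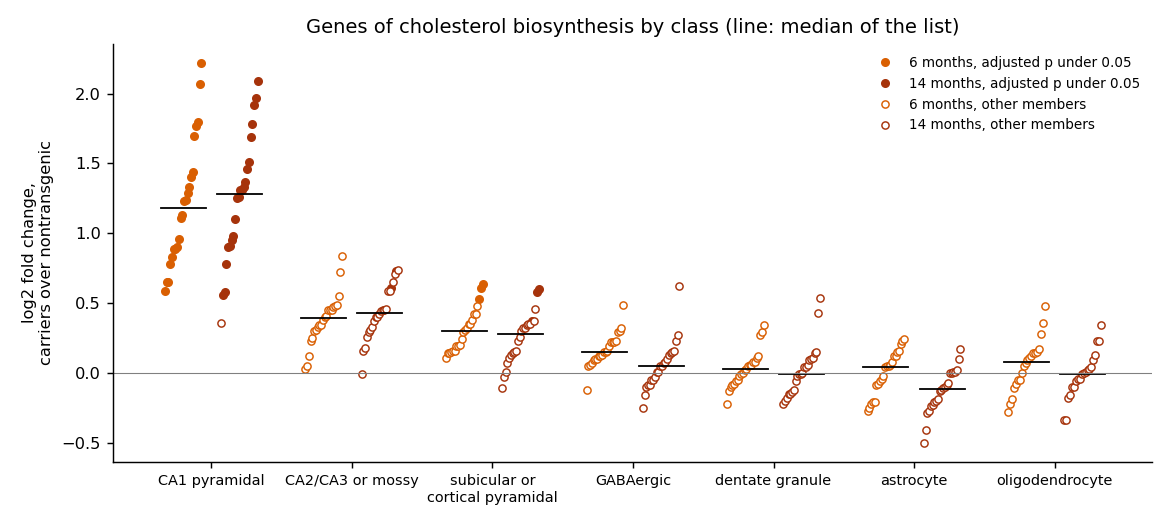
Log2 fold change of carriers against nontransgenic mice, 1 point per cholesterol synthesis gene, in each tested class at both ages, filled where the gene passed, with lines at list medians. In CA1 neurons 22 of 22 genes passed at 6 months and 21 of 22 at 14 months, with medians of 1.18 and 1.28.

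Thy1 rose in all 10 classes at both ages. Outside CA1 it was at 6 months higher by 1.84 ± 0.11 in subicular or cortical neurons, 1.70 ± 0.14 in dentate granule neurons, 1.40 ± 0.13 in CA2, CA3 or mossy neurons and 1.32 ± 0.15 in GABAergic neurons. In vascular or meningeal cells it was higher by 2.31 ± 0.22 in 11 of 11 strains. In 14-month carriers the class with fewest Thy1 UMIs per nucleus, among the 9 other than microglia, had 0.710 and the median class 1.04, so RNA from neurons is not excluded as the source of the rise in glia and vascular or meningeal cells. Genes whose UMIs lay mostly in microglia followed in neurons, such as Trem2 in CA1 (2.64 ± 0.28, 13 of 13 strains), Cst7 in dentate granule neurons (2.74 ± 0.30, 13 of 13) and Tyrobp, which encodes the Trem2 adaptor, in CA2, CA3 or mossy neurons (2.41 ± 0.31, 12 of 13). Microglial markers as a set were 0.28 higher in dentate granule nuclei of carriers (12 of 13 strains, adjusted p = 0.037). Over 11 such genes the class with most UMIs per nucleus, among the 9 other than microglia, had a median of 1.26 times the UMIs of the median class in 14-month carriers. Subicular or cortical neurons had lower Vgf, a neuropeptide precursor gene (-0.61 ± 0.12, adjusted p = 0.00643, 12 of 13 strains), and higher Nsdhl (0.61 ± 0.11) and Mvd (0.64 ± 0.13). GABAergic neurons had lower Mme, the gene of the peptidase neprilysin (-0.69 ± 0.13, 0.0107, 11 of 13). The calls of Vgf and Mme were lost without C57BL6J and C57BL6JxD2Gpnmb.

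Complement genes rose in oligodendrocytes (4 of 6, 4 adjusted over the list alone, 4.01e-09 with an estimated correlation) and astrocytes (5 of 5, 5 and 4.01e-09). The members were C4b, the C1q chain genes C1qa, C1qb and C1qc, whose UMIs lay mostly in microglia, and in astrocytes Clu; in microglia 3 of 8 rose (4 adjusted over the list alone, list adjusted p = 0.191). Activity-regulated genes were lower in GABAergic neurons (0 of 24 called, 12 lower adjusted over the list alone, 0.00107 with an estimated correlation; median -0.38). They were lower too in subicular or cortical neurons (1 of 27, Vgf, and 2; 0.0248; median -0.31) and in CA2, CA3 or mossy neurons (0 of 23 and 1; 0.0237; median -0.22). In dentate granule and CA1 neurons the call was lost, with adjusted p = 0.0652 and 0.0778 with an estimated correlation (0 of 27 called in each, 2 and 5 lower adjusted over the list alone). The Alzheimer's risk list was higher in CA1 neurons (2 of 22, 4 adjusted over the list alone, 0.00767 with an estimated correlation), CA2, CA3 or mossy neurons (1 of 21 and 1, 0.0237), and subicular or cortical neurons (2 of 24 and 3, 0.000157). It was also higher in oligodendrocytes (2 of 20 and 3, 0.00662) and astrocytes (4 of 19 and 4, 0.00208). Its call was lost in dentate granule (1 of 22 and 1, adjusted p = 0.0751 with an estimated correlation) and GABAergic neurons (1 of 21 and 1, 0.0854). Few members passed, in neurons among them the microglial gene Trem2, so the whole list is not shown to rise. In microglia 3 of 25 risk genes rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.774), including Cd33 (-0.65 ± 0.12) and Cass4 (-1.22 ± 0.22).

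Several lists showed no change at 6 months that held with an estimated correlation. Oxidative phosphorylation genes had negative medians in all 7 classes tested, from -0.22 to -0.10, with 0 of 30 called and adjusted p from 0.205 to 0.596 with an estimated correlation. No glutamatergic synapse gene of 32 was called in any neuronal class (adjusted p from 0.258 to 0.782), and no heat shock gene in 8 classes (0.209 to 0.964). Unfolded protein response genes were called in none of 8 classes, with adjusted p = 0.351 with an estimated correlation in astrocytes, where 2 were higher adjusted over the list alone, as was 1 in CA1 neurons. Immature granule neuron genes (0 of 6, adjusted p = 0.996), proliferation genes in precursors (0 of 6, 0.996) and vascular and blood-brain barrier genes (0 of 16, 0.413) were not called. In microglia the only proliferation gene tested was not called (list adjusted p = 0.417), but was higher when adjusted over the list alone (0.54). Adjusted over the list alone, 0 members changed in the glutamatergic, heat shock, oxidative phosphorylation, immature granule and vascular lists.

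At 14 months more genes passed in total, though fewer in astrocytes, precursors and GABAergic neurons than at 6 months. Microglial Cst7 was at 59.3 ± 21.0 CPM (SD, n = 12) against 0.286 ± 1.07 CPM (n = 14), Dkk2 at 198.0 ± 85.8 against 1.23 ± 2.18 CPM and P2ry12 at 435.5 ± 83.2 against 750.4 ± 135.2 CPM. Gpnmb in microglia was at 124.8 ± 71.9 against 2.47 ± 5.31 CPM. C4b in oligodendrocytes was at 523.7 ± 201.5 against 50.9 ± 19.1 CPM and the class I gene H2-D1 at 125.1 ± 68.9 against 14.4 ± 4.94 CPM. In CA1 neurons Sqle was at 43.5 ± 11.2 against 16.1 ± 3.84 CPM, and Cd34, a surface sialomucin gene, at 13.4 ± 3.86 against 23.5 ± 4.97 CPM.

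Of the 111157 tests 3337 passed at 14 months (edgeR), 2079 higher and 1258 lower in carriers, in 2796 different genes. Microglia gave 2054 (1135 higher, 919 lower), CA1 pyramidal neurons 488 (358 and 130), oligodendrocytes 313 (267 and 46), and subicular or cortical pyramidal neurons 278 (139 and 139; with RLE scaling 63.6% of 338 were higher). There were 88 in astrocytes (80 and 8), 62 in oligodendrocyte precursors (57 and 5), 36 in dentate granule neurons (29 and 7), 9 in CA2, CA3 or mossy neurons (6 and 3), 7 in GABAergic neurons (6 and 1) and 2 in vascular or meningeal cells. Without the 7 libraries that stood apart, 2032 passed in 9 classes. In a fit of the 14-month libraries alone, 1731 passed, among them 78 in subicular or cortical and 3 in dentate granule neurons. Leaving out 1 strain gave 19 (without C57BL6JxBXD161) to 206 (without C57BL6JxBXD33) in dentate granule neurons, 94 to 606 (same strains) in subicular or cortical neurons and 217 (without C57BL6JxBXD65) to 772 (without C57BL6JxBXD33) in oligodendrocytes. Within dentate granule and subicular or cortical neurons the clusters differed in weight between groups: at 14 months cluster 3 of the dentate class held 10.5% of nontransgenic and 5.64% of carrier nuclei, and cluster 10 of the subicular class held 2.46% and 4.92%.

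**Figure D4:**
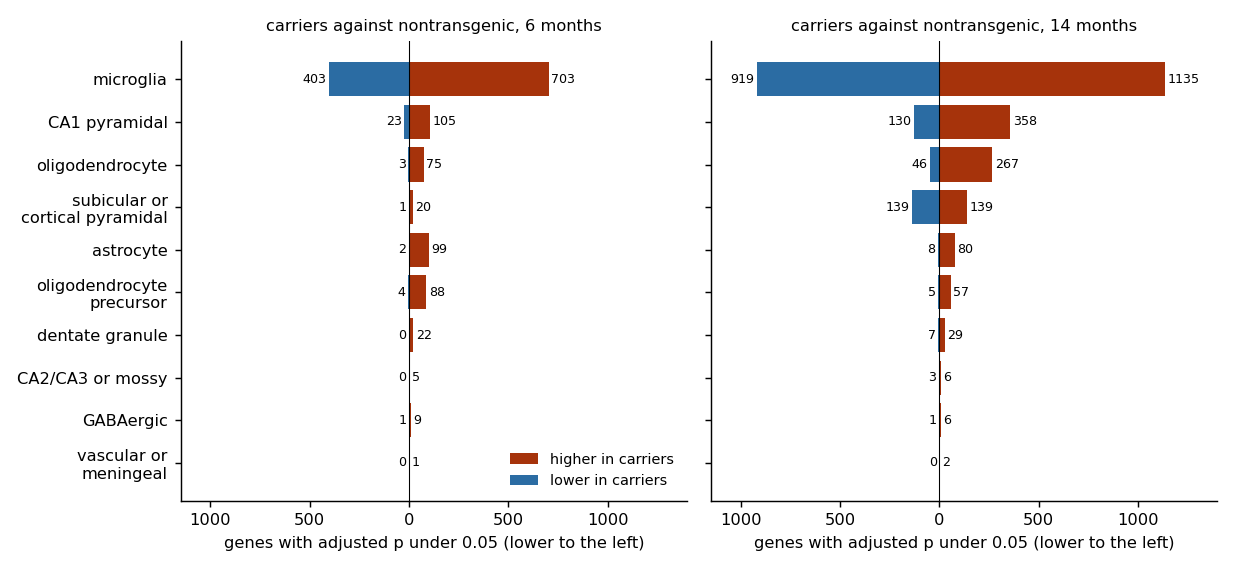
Number of genes higher and lower in carriers than in nontransgenic mice in each class at 6 and 14 months, as bars. Microglia have 1106 genes at 6 months and 2054 at 14 months, and vascular or meningeal cells 1 and 2.

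In microglia at 14 months the smallest p among higher genes belonged to Etl4 (3.33 ± 0.15, adjusted p = 1.79e-22), Olfr111 (3.35 ± 0.19, 1.35e-18), the fatty acid synthesis gene Acaca (2.75 ± 0.16, 1.54e-18) and Cst7 (6.69 ± 0.43, 1.54e-18), each in 12 of 12 strains. Among lower genes they belonged to Bank1 (-1.80 ± 0.15, 2.97e-13), Nhs (-2.61 ± 0.22, 8.92e-13), the uroplakin gene Upk1b (-1.96 ± 0.17, 1.09e-12) and the noncoding RNA gene Trp53cor1 (-1.60 ± 0.14), each in 12 of 12 strains. Of 37 plaque-associated genes 34 rose, and 35 adjusted over the list alone (6.55e-06 with an estimated correlation; median 1.77), with Gpnmb at 5.88 ± 0.59 and Dkk2 at 6.87 ± 0.46, both in 12 of 12 strains. The Gpnmb effect was not shown to differ between ages (difference 2.51 ± 1.58, adjusted p = 0.688). Of 24 homeostatic genes 21 fell, and 21 adjusted over the list alone (0.00177 with an estimated correlation; median -0.71), including Cx3cr1 (-0.73 ± 0.08), Slc2a5 (-1.43 ± 0.16), P2ry12 (-0.79 ± 0.09) and the crystallin gene Crybb1 (-1.97 ± 0.18), each in 12 of 12 strains. Macrophage markers were lower in microglial nuclei of carriers (-1.53, adjusted p = 0.0423) and vascular markers higher (1.10, 0.0476).

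**Figure D5:**
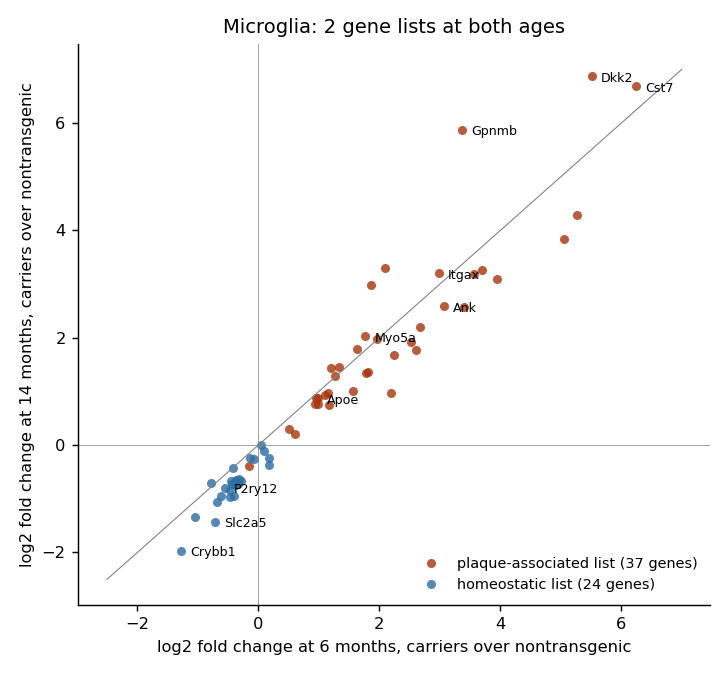
Log2 fold change in microglia at 14 months against that at 6 months, 1 point per gene of the plaque-associated and the homeostatic list. At 14 months 34 of 37 plaque-associated genes rose and 21 of 24 homeostatic genes fell.

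Interferon-response genes rose at 14 months in oligodendrocytes (5 of 8, 7 adjusted over the list alone, 7.09e-05 with an estimated correlation; median 0.91), astrocytes (3 of 13 and 11, 1.94e-05; 0.65) and microglia (16 of 18 and 17, 0.0217; 1.25). In vascular or meningeal cells 0 of 10 were called and the list call was lost, with adjusted p = 0.176 with an estimated correlation. Antigen presentation genes rose in oligodendrocytes (5 of 6 and 5, 1.57e-07; median 2.65), astrocytes (4 of 6 and 5, 5.35e-06; 0.89) and microglia (8 of 10 and 8, 0.00193; 1.29). Examples were the class I transactivator gene Nlrc5 (2.81 ± 0.26 in oligodendrocytes, 1.80 ± 0.25 in astrocytes), B2m, the class I light chain gene (1.87 ± 0.23 in oligodendrocytes), and Cd74 (3.54 ± 0.41 in microglia, 12 of 12 strains). Complement genes rose in oligodendrocytes (4 of 6 and 4, 1.94e-05) and astrocytes (4 of 5 and 5, 3.74e-07), again C4b with C1q chain genes; in microglia 1 of 8 rose (1 adjusted over the list alone, adjusted p = 0.923).

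Oligodendrocytes at 14 months were led by C4b (3.39 ± 0.17, adjusted p = 2.69e-18), H2-D1 (3.01 ± 0.20, 4.38e-15), the complement lectin pathway protease gene Masp1 (3.30 ± 0.25, 2.83e-13) and H2-K1 (2.49 ± 0.20, 3.52e-13), each in 12 of 12 strains. Of 12 disease-associated oligodendrocyte genes 9 rose, and 9 rose and 1 fell adjusted over the list alone (6.51e-09 with an estimated correlation; median 1.85). Among 21 myelin genes Cldn11 rose (0.33 ± 0.10, 10 of 12 strains) and Cnp fell (-0.42 ± 0.11, 10 of 12), also when adjusted over the list alone (list adjusted p = 0.0981). The tubulin glutamylase subunit gene Tpgs1 (-0.77 ± 0.17, 0.00231, 10 of 12) and the histone gene H2afv (-0.51 ± 0.12, 0.00551, 12 of 12) were lower. Precursors had higher C4b (3.28 ± 0.22, 1.44e-18), Zfp804b (2.19 ± 0.24, 7.16e-08) and the metalloprotease gene Adamts9 (1.37 ± 0.18, 8.63e-08), each in 12 of 12 strains. They had lower Cntn3, a contactin gene (-0.48 ± 0.11, 0.00872, 11 of 12). Precursor markers were 0.27 higher in oligodendrocyte nuclei of carriers (11 of 12 strains, adjusted p = 0.0423). The calls of Cldn11, Cnp, H2afv and Cntn3 were lost without the 7 libraries.

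Astrocytes at 14 months had higher Enox1 (1.02 ± 0.10, adjusted p = 1.18e-09, 12 of 12 strains), Ggta1, a galactosyltransferase gene (1.62 ± 0.17, 2.48e-09, 12 of 12), Gfap (1.27 ± 0.13, 2.85e-09, 12 of 12) and H2-D1 (1.74 ± 0.19, 1.45e-08, 11 of 12). The transcription factor gene Etv4 (-0.57 ± 0.11, 0.000755, 11 of 12) and the thyroid hormone transporter gene Slco1c1 (-0.65 ± 0.12, 0.000771, 11 of 12) were lower, the latter not without the 7 libraries. Of 23 reactive genes 9 rose, and 15 adjusted over the list alone (1.94e-05 with an estimated correlation; median 0.45), including Serpina3n (2.09 ± 0.31, 12 of 12). Homeostatic genes had 0 of 17 called, 3 lower adjusted over the list alone, and a list call that was lost, with adjusted p = 0.117 with an estimated correlation.

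CA1 neurons at 14 months had higher Thy1 (2.39 ± 0.08, adjusted p = 5.28e-28, 12 of 12 strains), Nsdhl (1.78 ± 0.13, 7.04e-14, 11 of 12), Sqle (1.37 ± 0.13, 7.03e-11, 12 of 12) and Dhcr7 (1.31 ± 0.13, 2.07e-10, 12 of 12). Of the 22 cholesterol synthesis genes 21 rose, and 22 adjusted over the list alone (6.51e-09 with an estimated correlation; median 1.28, and 1.08 with 18 called without the 7 libraries). The list was higher in CA2, CA3 or mossy neurons (2 of 22 and 17, 0.000169; median 0.43) and subicular or cortical neurons (3 of 22 and 11, 0.0305; 0.28). It was not in GABAergic neurons, dentate granule neurons or oligodendrocytes (adjusted p = 0.243, 0.845 and 0.769) or, with an estimated correlation, astrocytes (0.364; 1 lower adjusted over the list alone). Cd34 (-0.83 ± 0.14, 5.91e-05, 12 of 12), the cilia gene Cfap100 (-0.75 ± 0.13, 0.000128, 10 of 12) and Arhgef26 (-0.51 ± 0.10, 0.00154, 10 of 12) were lower in CA1. In dentate granule neurons Thy1 rose by 1.65 ± 0.14 and Etv5, a growth factor-responsive transcription factor gene, fell (-1.02 ± 0.21, 0.0105, 11 of 12), as did Scg5 of the secretory granule (-0.32 ± 0.07, 0.0105, 10 of 12). Subicular or cortical neurons had lower Mir670hg (-0.68 ± 0.11, 0.000416, 12 of 12), the GTPase gene Rem2 (-1.11 ± 0.20, 0.00232, 10 of 12) and Vgf (-0.69 ± 0.13, 0.00336, 11 of 12). GABAergic neurons had lower Alkal2, a receptor tyrosine kinase ligand gene (-1.05 ± 0.19, 0.00358, 11 of 12). The calls of Etv5 and Scg5 were lost without C57BL6J and C57BL6JxD2Gpnmb, and those of Alkal2 and Scg5 with library run as a term. No call in GABAergic neurons, that of Alkal2 included, held in a fit of the 14-month libraries alone. Precursor markers were 0.25 higher in CA1 nuclei of carriers (11 of 12 strains, adjusted p = 0.0423).

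The other lists at 14 months held for few classes. Oxidative phosphorylation genes had medians from -0.47 to -0.27 in the 7 classes tested, and the call held in CA2, CA3 or mossy neurons (0 of 30 called, 0 adjusted over the list alone, adjusted p = 0.0479 with an estimated correlation). It was lost in dentate granule (0 called, 6 lower adjusted over the list alone, adjusted p = 0.0853 with an estimated correlation), subicular or cortical (2 called, 24, 0.0853), GABAergic (0, 2, 0.0783) and CA1 neurons (0, 2, 0.171), in oligodendrocytes (0, 16, 0.145) and in astrocytes (0, 0, 0.145). The 2 called were Cox5a (-0.49 ± 0.13) and Ndufb8 (-0.83 ± 0.23) of the respiratory chain, and neither call held without the 7 libraries. Activity-regulated genes were lower in GABAergic neurons (0 of 24 called, 6 lower and 1 higher adjusted over the list alone, 0.0479 with an estimated correlation; median -0.37). Their calls were lost in subicular or cortical (5 of 27 lower, 8 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation), dentate granule (0 and 1, 0.145), CA1 (2 and 2, 0.26) and CA2, CA3 or mossy neurons (0 and 0, 0.0732). By few members, the risk list was higher in subicular or cortical neurons (2 of 24, 3 adjusted over the list alone, 0.0454 with an estimated correlation) and astrocytes (1 of 19 and 2, 0.00362). Its call was lost in dentate granule neurons (1 of 22 and 1, adjusted p = 0.0853 with an estimated correlation). In CA1 neurons 3 of 22 rose, including Trem2 and App (the latter not without the 7 libraries), with a list adjusted p of 0.0876, and in CA2, CA3 or mossy (1 of 21), GABAergic (1 of 21) neurons and oligodendrocytes (2 of 20) adjusted p was 0.12, 0.222 and 0.0756; adjusted over the list alone, 3, 1, 1 and 4 rose in these classes. In microglia 4 of 25 rose and 8 fell, 4 and 10 adjusted over the list alone (adjusted p = 0.114).

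Unfolded protein response genes were lower at 14 months by the preset correlation in 7 of 8 classes, and none of these calls held, with adjusted p from 0.0674 to 0.333 with an estimated correlation. The members that fell were Asns (-1.04 ± 0.27) and Herpud1 (-0.56 ± 0.15) in microglia and Calr (-0.54 ± 0.14) in subicular or cortical neurons, and adjusted over the list alone 4 fell in GABAergic neurons, 2 in microglia and 1 in subicular or cortical neurons. Heat shock genes had 2 lower of 15 in microglia, Hspa8 (-0.70) and Dnaja1 (-0.43), 0 adjusted over the list alone, and a list adjusted p of 0.0762 there, and 0.349 with an estimated correlation in dentate granule neurons. Glutamatergic synapse genes were not called as a list in any neuronal class (adjusted p from 0.0602 to 0.442), and 3 calls of single members were Rims1 (0.20 ± 0.06 in CA1 and 0.22 in subicular or cortical neurons) and Nrgn (-0.36 ± 0.09 in CA1). The calls of Herpud1, Calr, Dnaja1, Rims1 and Nrgn were lost without the 7 libraries, and that of Hspa8 with library run as a term. Adjusted over the list alone, 4 rose and 1 fell in CA1, 1 rose and 2 fell in subicular or cortical and 1 rose in dentate granule neurons. Proliferation genes in precursors had 0 of 6 called, 3 higher adjusted over the list alone, and a lost list call (adjusted p = 0.0853 with an estimated correlation; median 0.97). Not called were immature granule neuron genes (adjusted p = 0.326) and proliferation in microglia (0.527). No vascular and blood-brain barrier call held (0 of 16, 0.348 with an estimated correlation). The median and the list test had opposite signs for immature granule neuron genes at 6 months (median 0.05, test lower), for heat shock genes in subicular or cortical neurons (-0.01, higher) and unfolded protein response genes in GABAergic neurons (-0.05, higher) at that age. At 14 months the mean and the test did for complement in microglia (0.01, lower), cholesterol synthesis in dentate granule neurons (0.02, lower) and glutamatergic synapse genes in CA2, CA3 or mossy (-0.01, higher) and GABAergic neurons (-0.03, higher).

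The genotype effects at the 2 ages overlapped in separate mice. In fits of each age alone, 627 of the 903 microglial genes called at 6 months were called in the same direction at 14 months, where 1126 were called and independent lists would share 85.5. CA1 neurons shared 66 genes of 89 and 283 (1.52 of independent lists), oligodendrocytes 42 of 53 and 132, astrocytes 21 of 74 and 46, and precursors 15 of 51 and 47. No gene was called in opposite directions in any of the 10 classes, whether the ages were fitted alone or together.

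Which genes had a genotype effect that differed between ages was tested directly, and 4 were called. As many were called in 2 of 25 splits of the libraries by genotype and age within strains, the real one included (highest of the others 7), so chance is not excluded. The count was 0 without C57BL6JxBXD39 and 7 without C57BL6JxBXD113, and it was 11 with DESeq2, 62 with no filter on low counts and 0 with the stricter nucleus filter. In oligodendrocytes, Lhfpl3 was at 29.6 and 39.6 CPM in nontransgenic mice and carriers at 6 months and at 21.3 and 62.1 CPM at 14 months (log2 difference of effects 1.22 ± 0.21, adjusted p = 0.00572, 11 of 12 strains). The sorting nexin gene Snx10 (1.20 ± 0.24, 0.0339, 11 of 12) and Piezo2, a mechanosensitive channel gene (1.47, 0.0459, 12 of 12), followed in the same class. In precursors the cadherin gene Cdh18 was at 724.7 CPM in 14-month carriers against 471.0 CPM in nontransgenic mice of that age, and at 369.1 against 355.3 CPM at 6 months (0.59 ± 0.12, 0.0434, 12 of 12). Piezo2 was named after its values were seen. Lhfpl3 is itself a precursor marker, and precursor markers were 0.27 higher in oligodendrocyte nuclei of 14-month carriers. The calls of Lhfpl3, Snx10 and Cdh18 were lost without the 7 libraries.

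The other 8 classes had 0 genes by edgeR in this contrast, with 98 (vascular or meningeal) to 914 (subicular or cortical) genes at unadjusted p under 0.05, and DESeq2 called 1 gene in CA1 neurons and 0 in the rest. No list kept its call for the difference with an estimated correlation; the lowest adjusted p were 0.18 for antigen presentation in oligodendrocytes, homeostatic microglia and homeostatic astrocytes.

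Age alone was examined in nontransgenic mice, between 6 and 14 months in 13 strains. In dentate granule neurons the axon guidance receptor gene Robo1 was at 64.5 ± 12.6 CPM (SD, n = 14) at 14 months against 132.2 ± 20.9 CPM (n = 13) at 6 months, and the kinase gene Camk2d at 76.1 ± 11.7 against 39 ± 10.0 CPM. In oligodendrocytes the cadherin gene Cdh8 was at 167.4 ± 26.8 against 64.6 ± 15.3 CPM, and C4b at 50.9 ± 19.1 against 18.2 ± 7.43 CPM. In astrocytes Csmd1, which encodes a complement-regulating membrane protein, was at 250.1 ± 55.8 against 422.8 ± 67.5 CPM.

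Of the 111157 tests 67 passed (edgeR), 44 higher and 23 lower at 14 months: 27 in dentate granule neurons (18 higher, 9 lower), 18 in oligodendrocytes (13 and 5), 18 in astrocytes (9 and 9), 3 in CA1 neurons and 1 in CA2, CA3 or mossy neurons. The other 5 classes had 0, with 479 genes at unadjusted p under 0.05 in subicular or cortical neurons, 405 in GABAergic neurons, 393 in precursors, 413 in microglia and 108 in vascular or meningeal cells, and DESeq2 called 0 in each of these classes. The dentate genes were led by Robo1 (ENSMUSG00000022883; -1.04 ± 0.07, adjusted p = 8.71e-14, lower in 13 of 13 strains), and Camk2d (0.96 ± 0.09, 3.15e-10). Further were the glutamate receptor gene Grm8 (0.60 ± 0.08, 1.81e-05) and the neuregulin gene Nrg1 (0.44 ± 0.07, 8.93e-05), and like Camk2d each was higher in 13 of 13 strains. Fibrillin gene Fbn2 was lower (-0.60 ± 0.12, 0.015, 12 of 13), a call that was lost without the strain term.

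Oligodendrocyte genes were led by Cdh8 (ENSMUSG00000036510; 1.38 ± 0.10, adjusted p = 2.5e-15), the chloride channel gene Clic5 (1.68 ± 0.19, 2.61e-08) and C4b (1.44 ± 0.20, 1.5e-05), each higher in 13 of 13 strains. Lower were Nckap5 (-1.06 ± 0.16, 7.05e-05) and the protocadherin gene Pcdh7 (-0.99 ± 0.17, 0.000841), each in 13 of 13 strains. Astrocytes had lower Csmd1 (-0.78 ± 0.11, 1.38e-05), the catenin gene Ctnna2 (-0.42 ± 0.07, 0.000466) and the receptor scaffold gene Grip1 (-0.74 ± 0.14, 0.00866), each in 13 of 13 strains. They had higher Cped1 (0.69 ± 0.11, 0.000208, 13 of 13) and C4b (0.73 ± 0.15, 0.0134, 11 of 13). The calls of Csmd1 with doublets kept and of C4b in astrocytes without the 7 libraries were lost.

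Of the lists, immature granule neuron genes were lower with age in dentate granule neurons (0 of 6 called, 2 lower adjusted over the list alone, adjusted p = 0.000914, and 0.0481 with an estimated correlation; median -0.31). Camera called 33 of 68 pairs of a list and a class for age in nontransgenic mice, and no other call held, with adjusted p of 0.45 and above with an estimated correlation. With labels exchanged within strains, 1 of the other 24 splits also gave 1 such pair, so chance is not excluded. Median log2 changes stayed between -0.16 and -0.08 for heat shock genes and between -0.12 and -0.06 for oxidative phosphorylation genes over their classes, with 0 members called.

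Age within carriers was compared in 12 strains. In oligodendrocytes Cdh8 was at 211.1 ± 28.2 CPM at 14 months (SD, n = 12) against 64.0 ± 10.7 CPM at 6 months (n = 14). In microglia the cation channel gene Trpc4 was at 86.7 ± 34.9 against 33.2 ± 17.4 CPM, and Gpnmb at 124.8 ± 71.9 against 20.1 ± 25.1 CPM. Robo1 in dentate granule neurons was at 71.6 ± 8.06 against 136.8 ± 19.2 CPM, as in nontransgenic mice.

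In all, 361 of the tests passed in carriers (edgeR; 293 higher, 68 lower). The count ran from 193 (without C57BL6JxBXD161) to 711 (without C57BL6JxBXD33), and was 819 with DESeq2, 129 without the 7 libraries and lower than 193 with library run as a term. There were 144 in oligodendrocytes (133 and 11), 57 in microglia (46 and 11), and 42 in subicular or cortical neurons (16 and 26; with RLE scaling 59.4% of 32 were higher). There were 31 in dentate granule neurons (27 and 4), 31 in CA1 neurons (26 and 5), 28 in astrocytes (20 and 8), 26 in precursors (24 and 2), 1 in CA2, CA3 or mossy neurons and 1 in GABAergic neurons. There were 0 in vascular or meningeal cells (186 at unadjusted p under 0.05, 0 by DESeq2). Higher with the smallest p were Cdh8 (1.73 ± 0.10, adjusted p = 7.36e-19) and the transcriptional coactivator gene Eya4 (1.18 ± 0.11, 2.09e-10) in oligodendrocytes, and Cdh18 (0.97 ± 0.08, 1.56e-13) and the muscarinic receptor gene Chrm3 (1.23 ± 0.17, 1.03e-05) in precursors, each in 12 of 12 strains. So were Trpc4 (1.52 ± 0.19, 2.04e-06) in microglia and Grm8 (0.89 ± 0.09, 1.08e-09) in dentate granule neurons, each in 12 of 12 strains. Gpnmb was higher in microglia in 11 of 12 strains (2.80 ± 0.35, 2.04e-06), a call that was lost with library run as a term. Camk2d (0.90 ± 0.09, 11 of 12) was higher and Robo1 (-0.94 ± 0.08, 2.21e-11, 12 of 12) lower in dentate granule neurons.

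In carriers 3 lists held with an estimated correlation, but with labels exchanged within strains 1 of the other 24 splits gave 7, so chance is not excluded. Antigen presentation in oligodendrocytes (3 of 6 higher, 5 adjusted over the list alone, adjusted p = 0.0187 with an estimated correlation; median 1.02) and disease-associated oligodendrocyte genes (5 of 12 and 8, 0.0187; 0.65) were higher. Immature granule neuron genes were lower in dentate granule neurons (0 of 6 called, 2 lower adjusted over the list alone, 0.0275; -0.31). Homeostatic microglial genes had 1 of 24 lower, 10 adjusted over the list alone, and adjusted p = 0.0945 with an estimated correlation. Whether ageing differed between genotypes is the test of the difference between ages above, which called 4 genes.

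Strain differences were tested to describe the genetic panel, with the 4 groups as a term. They gave 3035 calls in 1534 different genes (edgeR F test over strains). These were 784 in dentate granule neurons, 488 in CA1, 428 in subicular or cortical, 413 in GABAergic and 309 in CA2, CA3 or mossy neurons. Glia had fewer, with 243 in oligodendrocytes, 191 in astrocytes, 90 in microglia and 84 in precursors, and vascular or meningeal cells had 5. Cfap54, a cilia gene, ranged in dentate granule neurons from 19.6 ± 3.11 CPM in C57BL6JxBXD66 (SD, 2 libraries) to 120.4 ± 10.2 CPM in C57BL6JxD2Gpnmb (4 libraries; adjusted p = 6.8e-26 from edgeR). The ubiquitin ligase gene Rnf121 ranged in CA1 neurons from 40.9 ± 7.79 CPM in C57BL6JxBXD53 to 237.9 ± 49.3 CPM in C57BL6JxBXD113 (edgeR adjusted p = 1.07e-25). In oligodendrocytes the endocytosis gene Fcho1 ranged from 2.62 ± 2.67 CPM in C57BL6JxBXD33 to 119.8 ± 17.3 CPM in C57BL6JxBXD99 (8.72e-25). Gpnmb differed between strains in dentate granule neurons (5.23 ± 3.49 to 20.3 ± 3.43 CPM, adjusted p = 0.00137) and was not called in microglia (adjusted p = 0.489). Sequence differences between a strain and the reference genome can change how many reads are counted, and this was not tested. Calb1, a calcium buffer gene of granule and pyramidal neurons, was not called for genotype in dentate granule neurons (-0.08 ± 0.08 at 6 months and -0.20 ± 0.08 at 14 months, adjusted p = 0.9999 and 0.276). It was not called in CA1 neurons either (-0.03 ± 0.12 and 0.13 ± 0.13, adjusted p = 0.985 and 0.648).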

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

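The tests of RNA from other cells, of a differing segment on chromosome 3 and of libraries of low depth were chosen only after the results were seen; the exchanges of labels and the shuffles of gene order were planned.

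A test of the interaction of genotype and age drew attention to 4 genes and 1 class share, because their genotype effects differed between the ages. In oligodendrocytes these were Lhfpl3 (log2 difference of effects 1.22), Snx10 (1.20) and Piezo2 (1.47), and in oligodendrocyte precursors Cdh18 (0.59). The share of CA1 pyramidal neurons was the fifth, with a log2 difference of -0.75; its call was lost with the centred log ratio, at resolution 2.0, without C57BL6J and C57BL6JxD2Gpnmb, without the 7 libraries that stood apart and when any of 10 strains was left out. Among 25 splits of the libraries by genotype and age within strains, the real one included, 2 gave as many genes in total (4; highest of the others 7), 2 in oligodendrocytes (3; 4) and 2 in precursors (1; 1), so chance cannot be excluded for these genes.

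Microglial genes were higher in carriers in classes other than microglia. If RNA released by other cells during nuclei isolation were the source, each such gene would be added to every class at a similar level. Over 11 such genes the highest other class had a median of 1.26 times the UMIs of the median class (1.13 to 2.42). Selection left out genes with 1 raised class (Cd9 at 7.06), so this evenness decides little. RNA from other cells stays a candidate explanation for the microglial genes in neurons, oligodendrocytes and astrocytes. It is argued against for Gfap and C4b in astrocytes, which gained more UMIs per nucleus there than in every neuronal class in at least 11 of 12 strains at 14 months and in 12 of 13 at 6 months, so a change within astrocytes stays open as a hypothesis. The smaller rise of Gfap in other classes was not tested in this way, nor was that of Thy1 outside neurons. For B2m, H2-D1 and H2-K1 in oligodendrocytes RNA from other cells stays open: the gain was above every neuronal class in 10, 9 and 9 of 12 strains at 14 months, and in 2, 6 and 8 of 13 at 6 months. Reads shared between H2-D1, H2-K1 and their relatives were not separated.

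Cholesterol synthesis genes rose mainly in CA1 pyramidal neurons. RNA from other cells would add a similar number of UMIs to every class, yet UMIs of the list per nucleus went from 4.43 to 9.13 in CA1 neurons at 6 months and from 4.70 to 10.6 at 14 months, a gain of 4.70 and 5.89 against at most 2.34 in any other class, and the gain was largest in CA1 neurons in 8 of 12 strains at 14 months. Libraries of low depth might distort the 14-month result, but without the 7 libraries the list median there was still 1.08. A response of CA1 neurons to the transgenes therefore stays open as a hypothesis. The rise was found and tested on the same data, and the product of the transgenes in CA1 neurons was not measured.

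Genes called outside microglia were concentrated on chromosome 3 between 60 and 80 Mb, where 18.2% of genes were called at 6 months against 2.05% over the genome, and 20% against 6.37% at 14 months. Chance placement of called genes is excluded at 6 months by 10000 shuffles of gene order (p = 0.0001, the smallest they can give). No shuffles were made for 14 months. A segment of chromosome 3 that differs between carriers and nontransgenic mice is a candidate explanation: the window ranked 1 of 477 at both ages, as it would for any cause that acts at both. Called genes there include Arhgef26 in CA1 neurons (-0.44 and -0.51), Mme in GABAergic neurons (-0.69 and -0.51), Fnip2 in CA1 neurons (0.45 and 0.46) and Tiparp in oligodendrocytes (0.51 and 0.64). Genotypes along the chromosome were not analysed here, so a segment and a regulatory response of neighbouring genes both stay open.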

How the results depend on the processing

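Omission of the 7 libraries that stood apart was chosen only after the data were seen; the other alternatives were planned. Over the alternatives run for them, named genes kept their side of the threshold in 7539 cases, with 225 weaker, 62 stronger and 0 reversed. List tests did so in 1948 cases, with 364 weaker, 55 stronger and 3 reversed, and class shares in 1306, with 37 weaker and 9 stronger. The causes of the changes below were not tested, except where a smaller number of strains or classes is given.

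For genotype at 6 months (1564 genes) the total fell outside 1.5 times only with the stricter nucleus filter, to 209 in the 7 classes it left testable. Genotype at 14 months (3337) gave 1731 with only the 2 groups of the contrast, 2032 without the 7 libraries and 967 with the stricter filter. Age in nontransgenic mice (67) gave 181 with no filter on low counts, 106 with library run, 29 with the stricter filter and 39 without C57BL6J and C57BL6JxD2Gpnmb. Age in carriers (361) gave 819 with DESeq2, 627 with no filter on low counts, 1.6e+02 with library run, 158 with the stricter filter, 129 without the 7 libraries and 224 without C57BL6J and C57BL6JxD2Gpnmb. The difference between ages (4) gave 11 with DESeq2, 62 with no filter, 0 with the stricter filter, and 1 without the 7 libraries and 1 without C57BL6J and C57BL6JxD2Gpnmb. Strain (3035) gave 5185 with DESeq2 and 5177 with no filter.

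Without the replicate block, that is without pairing by strain, age in nontransgenic mice gave 40 genes and the difference between ages 1, and an unpaired permutation test of shares gave 4 classes for age in carriers, where pairing gave 1.

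Pairs of a list and a class numbered 24, 19, 1, 3 and 0 with an estimated correlation, against 37, 43, 33, 38 and 29 with the preset one, for genotype at 6 and 14 months, age in nontransgenic mice, age in carriers and the difference. With fry, age in nontransgenic mice gave 1, age in carriers 12 and the difference 0. Age in nontransgenic mice gave 20 without the 7 libraries and 12 without C57BL6J and C57BL6JxD2Gpnmb, and the difference gave 18 with library run. With library run the difference for oxidative phosphorylation turned from lower to higher in CA1 (adjusted p = 0.04205, against 0.0125 without it), CA2, CA3 or mossy (0.03323 against 0.00447) and GABAergic neurons (0.03015 against 0.00311). Over the alternatives these ranged from 3.58e-07 to 0.735, 1.51e-06 to 0.697 and 3.12e-08 to 0.697.

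Class shares changed in 2 classes at 6 months, 4 at 14 months, 1 for age in carriers and 1 for the difference. The stricter filter, which removes most glia, gave 0 and 1 class for genotype at 6 and 14 months. Omission of C57BL6J and C57BL6JxD2Gpnmb gave 1, 2, 0 and 0. Without the 7 libraries, 14 months (7 strains, no exact p below 0.0156), age in carriers and the difference gave 0. The difference gave 0 with the centred log ratio, and with resolution 2.0 it and age in carriers both gave 0.

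Leaving out each strain in turn gave 1322 to 1612 genes for genotype at 6 months, 2594 to 4498 at 14 months, 47 to 70 for age in nontransgenic mice, 193 to 711 for age in carriers, 0 to 7 for the difference and 2613 to 3161 for strain. Age in carriers gave 193 without C57BL6JxBXD161, 197 without C57BL6J, 233 without C57BL6JxBXD65, 626 without C57BL6JxD2Gpnmb and 711 without C57BL6JxBXD33. The difference gave 0 without C57BL6JxBXD39, 1 without C57BL6JxBXD65, 2 without C57BL6J, C57BL6JxBXD124, C57BL6JxBXD33 or C57BL6JxBXD50 and 7 without C57BL6JxBXD113. Classes with a changed share numbered 1 to 3 at 6 months, 4 to 4 at 14 months, 1 to 4 for age in carriers (4 without C57BL6JxBXD113, 2 without C57BL6JxBXD124) and 0 to 1 for the difference. The astrocyte call at 6 months was lost when any of C57BL6J, C57BL6JxBXD113, C57BL6JxBXD161, C57BL6JxBXD39, C57BL6JxBXD83, C57BL6JxBXD99 or C57BL6JxD2Gpnmb was left out, and the CA1 call for the difference when any of C57BL6J, C57BL6JxBXD113, C57BL6JxBXD161, C57BL6JxBXD28, C57BL6JxBXD33, C57BL6JxBXD39, C57BL6JxBXD50, C57BL6JxBXD65, C57BL6JxBXD83 or C57BL6JxD2Gpnmb was.

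With RLE scaling the median of all genes moved by at most 0.0222, and the percent of called genes that were higher went from 50 to 63.6 in subicular or cortical neurons at 14 months (278 to 338 genes) and from 38.1 to 59.4 there for age in carriers (42 to 32). Of 316 named calls, 80 were lost without the 7 libraries and 0 changed direction. At 14 months these include App, Calr, Cd38, Cldn11, Cnp, Cox5a, H2afv, Herpud1, Ndufb8, Nrgn, Rims1 and Slco1c1. Precursors and vascular or meningeal cells could not be tested with at least 50 nuclei, nor astrocytes, microglia or vascular cells with the stricter filter, nor vascular cells without the 7 libraries. In simulated data 10.4% of log2 changes of 0.5 were recovered in vascular or meningeal cells and 53.7% in CA1 neurons.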

Other observations

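The comparison with the highest count of any class was chosen only after the results were seen; the other tests in this part were planned. They exchange all group labels within strains in 24 draws, with the real labels 25 splits. Chance means such draws, where genotype adds spread to age contrasts, which favours the real split there.

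Only the real split (1 of 25) reached the real count of genes for genotype at 6 months (1564, highest of the others 8) and 14 months (3337, 127). The same held for age in nontransgenic mice (67, 2) and carriers (361, 21). Chance is not excluded for the difference between ages (2 of 25 splits, 4, 7). Of the other 24 splits, 22, 22, 23, 23 and 23 gave 0 genes in the order above.

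Within classes, only the real split gave as many genes in the same class for genotype at 6 months in 10 classes (1 of 25 splits each; highest of the others 7 in subicular or cortical neurons, 1 in GABAergic neurons and 0 elsewhere). At 14 months this was so in 9 classes (highest of the others 36 in CA1 neurons, 74 in subicular or cortical neurons, 2 in precursors, 1 in vascular or meningeal cells and 0 in the rest) and not in CA2, CA3 or mossy neurons (2 of 25; 9 genes, highest of the others 15). It was so in the 5 classes with calls for age in nontransgenic mice (highest of the others 0), and in the 9 with calls for age in carriers (highest of the others 16 in oligodendrocytes, 3 in astrocytes, 2 in dentate granule neurons and 0 in the rest). Classes were tested only where genes were called, so this bound favours the real split. Counts passed the highest of any class in the other splits (7, 74, 2 and 16 in the order above) in 8, 5, 4 and 7 classes. Chance is left open in CA2, CA3 or mossy neurons (5 genes) and vascular or meningeal cells (1) at 6 months. At 14 months it is left open in dentate granule neurons (36), precursors (62), CA2, CA3 or mossy neurons (9), GABAergic neurons (7) and vascular or meningeal cells (2). With age it is left open at least in CA2, CA3 or mossy neurons of nontransgenic mice (1), and in these (1) and GABAergic neurons (1) of carriers.

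For lists at the preset correlation chance is not excluded for genotype at 6 months (2 of 25 splits, 37 pairs of a list and a class, highest of the others 41) and 14 months (2 of 25, 43, 44), age in nontransgenic mice (3 of 25, 33, 34) or the difference (7 of 25, 29, 35). Nor is it by the narrow lead for age in carriers (1 of 25, 38, 36). With an estimated correlation it can be excluded for genotype at 6 months (1 of 25; 24, 6) and 14 months (1 of 25; 19, 2), and not for age in nontransgenic mice (2 of 25; 1, 1), age in carriers (2 of 25; 3, 7) or the difference (25 of 25; 0, 14).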
